A study of Homo sapiens with 22 samples.

How the data were processed

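Each of the 22 arrays measured RNA of neutrophils from human blood (20 ng of input RNA per array, per the labels). The authors deposited 1 table of 54675 probe sets by 22 arrays, and its values are taken as log2 signals: nothing in the labels names the scale or the normalization, but their range is that of log2 of 16-bit scanner values. All log2 differences and folds rest on that reading. The 12 ex vivo arrays and the 10 volunteer arrays differ in mean and range, as if normalized separately, so no test crosses the 2 sets. The tools that made the deposited table are not given in the sources used here.

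The ex vivo arrays were grouped by stimulus (4 each), and the volunteer arrays by isolation method (5 each, paired by the volunteer given in the labels). The free-text descriptions of the 10 volunteer arrays mention GM-CSF and IFN-gamma, whereas their condition and source fields say unstimulated, and the latter were followed. The labels give the same subject to all ex vivo arrays, while the series design names 4 independent repeated experiments, so the ex vivo SD describes repeated experiments and not differences between people. The volunteer pairing comes from the labels: the correlation within a volunteer, once the method was fitted, was 0.063. Stimulated density-gradient samples named in the growth protocol were not analysed here.

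Probe sets were named from a table of the platform's probe sets and genes, and the gene identifiers compared with a RefSeq table of GRCh38.p14, which changed 0 names and was used for names alone. Of the probe sets 41091 name 1 gene (41037 of them matched by identifier), 1801 name several, 11721 name none and 62 are controls. For each gene the probe set with the highest mean over all 22 arrays was tested, which gave 19740 genes, 10511 of them with several probe sets. Genes of the Y chromosome and *XIST* were left out.

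Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. All 12 ex vivo arrays entered 1 fit without a block, which leaves 9 residual degrees of freedom, and the 10 volunteer arrays a fit with the volunteer as a block, which leaves 4. The median 95% confidence interval of a gene's difference reached 0.426 log2 units to either side in the ex vivo fit and 0.419 in the volunteer fit.

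The comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. There were 26 lists of 426 entries, 385 of them measured, and 11 genes stand in more than 1 list. They cover inflammatory cytokines and chemokines, NF-kB targets, type I interferon-stimulated genes, interferon-gamma target genes, MHC class I and class II genes, JAK-STAT feedback genes, Toll-like receptor signalling, resting receptors, primary granule genes, secondary and tertiary granule genes, the NADPH oxidase, the inflammasome and IL-1 family, apoptosis regulators, immediate-early genes, heat shock proteins, glycolysis and the hypoxia response, metallothioneins, cytosolic ribosomal proteins, and markers of monocytes, T, B and NK cells, eosinophils, platelets and erythroid cells. Lists were tested with limma's camera at a preset correlation between genes of 0.01, beside an estimated correlation and fry, which asks whether a list moves on balance one way and does not compare it with other genes. The rule names, per comparison, the 8 largest rises and falls among genes past the threshold whose arrays do not overlap (for the isolation methods, with the same sign in all 5 pairs) and whose higher mean exceeds the median gene, and from each list up to 4 members past the threshold, or else the 2 brightest. Other genes named were chosen after their values were seen, which the text says.

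Array quality was described by the 3 prime minus 5 prime log2 difference of control probe sets. For *ACTB* its mean was 2.67 in unstimulated blood, 3.43 after GM-CSF and IFN-gamma and 4.06 after LPS, and each pair of groups differed at the smallest p that 70 arrangements allow (two-sided exact permutation p 0.0286). For *GAPDH* the exact permutation p between ex vivo groups was 0.286 or more. Between the isolation methods *ACTB* was lower with microfluidics (1.15 against 1.31, p 0.125) and *GAPDH* higher (0.34 against 0.198, p 0.0625, the smallest that 5 pairs allow). No array repeated another: the highest correlation between any 2 was 0.979.

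The test was checked on simulated data with the spread of the real arrays and 50 changed genes per size. For LPS against unstimulated blood it called 16% of genes moved by 0.5 log2 units, 48% moved by 1, 84% moved by 2 and 100% moved by 4, and 0.0256% of unchanged genes. For the isolation methods the shares were 6%, 36%, 100% and 100%, with 0.0358% of unchanged genes. The Benjamini-Hochberg threshold depends on how many genes change, so these shares hold only for the simulated number of changed genes. A list of 15 genes moved by 1 log2 unit was found with the estimated correlation in both designs (camera, adjusted p 2.72e-05 and 0.0363), and 0 of 100 unmoved lists were called. These genes were simulated as independent and the lists drawn at random. The check therefore does not cover lists of correlated genes, such as the primary granule genes between the isolation methods (estimated correlation 0.80).

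Alternatives were quantile normalization, centring each array on its median, leaving out dim genes, the median over a gene's probe sets, no variance trend, array weights, the replicate number as a block, the 8 arrays of a contrast alone, a minimum of 1 log2 unit, the volunteer as a random block or no block, other list tests, splitting the unstimulated arrays, and leaving out each array or pair. List tests leaving out each volunteer pair, and 28 gene families picked by symbol pattern, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.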

Results

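Gene expression was measured on 22 whole-genome microarrays of RNA from human blood neutrophils, most of them captured in microfluidic cassettes. The ex vivo set holds 12 arrays: 4 of blood processed directly (unstimulated), 4 of blood incubated with lipopolysaccharide (LPS, a bacterial cell wall component, 50 ng/ml) and 4 of blood incubated with GM-CSF (20 ng/ml) and IFN-gamma (100 IU/ml), 2 cytokines that activate neutrophils. Both incubations lasted 16 h at 37 °C in 5% CO2. The volunteer set holds 10 arrays: from each of 5 volunteers, neutrophils were isolated in parallel by density gradient and by the microfluidic cassette. The deposited values are taken as log2 signals, and 19740 genes were tested. The number of arrays limits the precision: the median standard error of a difference was 0.196 log2 units between ex vivo groups and 0.178 between the isolation methods. Ex vivo means below the median gene of unstimulated blood (4.11 log2 units) are taken as near the background, which itself was not measured. Hybridization controls averaged 3.11 in the ex vivo arrays but 13.01 in the volunteer arrays. Reading 3.11 as background assumes that these controls were absent from the ex vivo arrays, which was not tested. On that assumption a fold against such a mean is a lower bound, written "at least", and log2 changes of such genes are compressed.

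What does LPS change in cells captured as neutrophils? Genes of inflammatory signalling rose, while receptors and granule genes of resting neutrophils fell. The share of other cell types is not given here. Which cells carry these transcripts therefore stays open, as it does after GM-CSF and IFN-gamma. *CCL20*, a chemokine, rose at least 493-fold from 3.24 ± 0.18 to 12.19 ± 0.04 log2 units (SD, n = 4 per group), and *IL12B*, a subunit of interleukin 12, rose at least 254-fold from 3.16 ± 0.05 to 11.15 ± 0.09. *IL6* (at least 226-fold), the chemokine receptor-like *CCRL2* (at least 407-fold) and the complement component *C3* (at least 211-fold) rose as well, and so did *COXFA4L3*, a gene related to a cytochrome c oxidase subunit (at least 959-fold). Among the genes that fell were the Wnt carrier *WLS* (at least 135-fold lower) and *FRAT1*, which acts in Wnt signalling (at least 112-fold lower). The surface peptidase *MME* (CD10), a marker of mature neutrophils, fell 94.4-fold from 11.08 ± 0.27 to 4.52 ± 0.35. In the limma test 3048 genes were higher and 2484 lower after LPS at an adjusted p under 0.05, of which 1634 and 1867 differed by at least 1 log2 unit. The excess of higher genes was not stable: it turned over among those, and the counts were 2522 higher and 2742 lower with each array centred on its median, and 2164 and 2346 with dim genes left out. The arrays of the 2 groups did not overlap for 5726 genes (29.0%), where chance gives 2.86%. In simulated data with the same spread and 50 changed genes per size, the test found 48% of genes that differed by 1 log2 unit. It found 84% of those that differed by 2. The real contrast called far more genes, which eases the adjusted threshold, so these shares do not hold for it.

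Most of the fixed list of inflammatory cytokines and chemokines rose after LPS: 22 of 23 genes were higher and 0 lower, with a median change of 4.40 log2 units (adjusted p 6.22e-25). *CCL2*, which attracts monocytes, rose by 7.42 ± 0.14 (SE). Of the NF-kB targets and feedback regulators 17 of 18 were higher and 1 was lower (median 2.95), among them *TRAF1* (7.15 ± 0.26), the urokinase gene *PLAU* (7.03 ± 0.26) and *CD83* (6.96 ± 0.32). Of 25 type I interferon-stimulated genes 22 were higher and 1 lower (median 2.50), with the antiviral genes *IFI44L* (5.05 ± 0.46), *OAS2* (3.92 ± 0.30) and *RSAD2* (3.89 ± 0.18). Of 21 interferon-gamma target genes 18 were higher and 2 lower (median 1.77): *IDO1*, which degrades tryptophan, rose by 6.21 ± 0.32 and *CD274*, which encodes PD-L1, by 4.33 ± 0.08. All 7 metallothioneins, which bind metal ions, were higher (median 4.63), including *MT1G* (5.02 ± 0.28) and *MT2A* (4.94 ± 0.24).

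Of 17 chemotactic and surface receptors of resting neutrophils 12 were lower and 4 higher (median -1.08): the interleukin 8 receptors *CXCR1* and *CXCR2* fell by 5.14 ± 0.31 and 4.66 ± 0.15. Of 15 secondary and tertiary granule genes 8 were lower and 3 higher (10 and 3 adjusted over the list alone, median -1.13). The protease *MMP25* fell by 5.08 ± 0.30 and the antimicrobial peptide gene *CAMP* by 3.42 ± 0.32, whereas the siderophore-binding *LCN2* rose by 2.73 ± 0.43. Among 16 Toll-like receptor signalling genes 5 were higher and 7 lower: the kinase genes *IRAK2* and *IRAK3* rose by 6.46 ± 0.29 and 2.92 ± 0.13, and the receptors *TLR5* and *TLR6* fell by 4.21 ± 0.21 and 3.28 ± 0.25. For that list the median (-0.16) and the mean (0.18) differed in sign, and so did those of the apoptosis regulators (6 higher and 7 lower of 16, median -0.20, mean 0.02). Of 12 MHC class II genes 3 were higher and 3 lower (median -0.02), with *HLA-DRA* at 2.01 ± 0.22 and *HLA-DPA1* at -1.37 ± 0.35.

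With the preset correlation, the list test (limma camera) passed 18 of 26 lists after LPS, and with an estimated correlation 7: the cytokines, the NF-kB targets, both interferon lists, the resting receptors, the secondary and tertiary granule genes and the metallothioneins. The NK cell markers, of which 10 of 13 were higher and 0 lower (median 2.21), lost their call with the estimated correlation (adjusted p 0.0694), although the cytotoxic genes *GZMB* (5.99 ± 0.32) and *PRF1* (5.65 ± 0.34) rose strongly. The primary granule genes (4 of 7 lower, median -1.71, with *CTSG* at -3.79 ± 0.40) lost theirs at 0.0779. The heat shock proteins (7 of 10 higher and 1 lower) and the JAK-STAT feedback genes (10 of 17 higher and 4 lower) both lost theirs at 0.0815. Monocyte markers (8 of 13 lower and 2 higher, median -1.45, with *FGL2* at -4.79 ± 0.17 and *CD163* at 3.85 ± 0.31), T cell markers (3 of 13 higher) and MHC class I genes (6 of 14 higher and 1 lower) lost theirs at 0.2856. The calls of the eosinophil markers (5 of 12 lower and 2 higher), erythroid markers (5 of 9 lower), platelet markers (3 of 12 lower) and cytosolic ribosomal proteins (6 of 25 lower and 2 higher) were lost at 0.1940, 0.2850, 0.3447 and 0.5267. No call was made for the B cell markers (2 higher and 4 lower of 12), the immediate-early genes (8 higher and 4 lower of 18), the NADPH oxidase (3 higher and 1 lower of 7), the inflammasome and IL-1 family (5 higher and 7 lower of 16) or glycolysis and the hypoxia response (5 higher and 4 lower of 17). Unstimulated blood was processed directly and stimulated blood after 16 h at 37 °C, so the stimulus and the incubation act together in this comparison. The *ACTB* 3 prime minus 5 prime difference moved along too (4.06 after LPS, 2.67 in unstimulated blood, two-sided exact permutation p 0.0286) and was not separated from them.

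What do GM-CSF and IFN-gamma change? They raised chemokines, like LPS, and with them the MHC class II genes, which present antigen. *CXCL10*, which attracts T cells, rose at least 337-fold from 3.31 ± 0.24 to 11.71 ± 0.13 log2 units (SD, n = 4 per group), and *CCL2* rose at least 333-fold from 3.81 ± 0.10 to 12.18 ± 0.08. The MHC class II genes *HLA-DQB1* and *HLA-DQA1* rose 24.2-fold and 20.0-fold, and the mannose receptor gene *MRC1*, a macrophage marker, rose 54.1-fold from 4.43 ± 0.17 to 10.19 ± 0.42. *MME* fell at least 150.4-fold, and *TNFRSF10C*, a decoy receptor for the death ligand TRAIL, fell 86.5-fold from 12.02 ± 0.10 to 5.58 ± 1.48. In all, 3045 genes were higher and 2316 lower in the limma test, of which 2161 and 1608 differed by at least 1 log2 unit. The arrays did not overlap for 5739 genes (29.1%), where chance gives 2.86%.

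Of 21 interferon-gamma target genes 19 were higher and 0 lower after GM-CSF and IFN-gamma (20 adjusted over the list alone, median 2.83, adjusted p 1.78e-21), among them *IDO1* (6.61 ± 0.32 SE) and *ANKRD22* (6.22 ± 0.42). Of 12 MHC class II genes 9 were higher and 0 lower (median 2.14), led by *HLA-DQB1* (4.60 ± 0.34) and *HLA-DRA* (3.61 ± 0.22). Inflammatory cytokines and chemokines (18 of 23 higher and 0 lower, median 2.92), NF-kB targets (16 of 18 higher and 1 lower, median 1.67) and type I interferon-stimulated genes (18 of 25 higher and 2 lower, median 1.54) rose as well, with *CCL4* at 6.86 ± 0.20, *CD83* at 6.94 ± 0.32 and *EPSTI1* at 3.92 ± 0.21. Heat shock proteins were higher in 9 of 10 genes and lower in 1 (median 1.37): the chaperone genes *HSPE1* and *HSP90AB1* rose by 3.28 ± 0.26 and 2.98 ± 0.27, and the inducible *HSPA6* fell by 2.87 ± 0.09. Resting receptors (12 of 17 lower and 3 higher, median -0.94) and secondary and tertiary granule genes (11 of 15 lower and 0 higher, median -1.53) fell, with *CXCR1* at -5.65 ± 0.31, *CSF3R*, the G-CSF receptor gene, at -3.53 ± 0.25 and *CAMP* at -3.75 ± 0.32.

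Of 26 lists 16 passed with the preset correlation and 8 with the estimated one: the interferon-gamma targets, the type I interferon-stimulated genes, the MHC class II genes, the cytokines, the NF-kB targets, the heat shock proteins, the resting receptors and the secondary and tertiary granule genes. The primary granule genes (4 of 7 lower, adjusted p 0.0613), the MHC class I genes (8 of 14 higher, 0.0764) and the JAK-STAT feedback genes (9 of 17 higher and 4 lower, 0.1318) lost their calls with the estimated correlation. In the last of these *SOCS1* and *CISH*, which restrain cytokine signalling, rose by 4.91 ± 0.24 and 3.14 ± 0.34. NK cell markers (6 of 13 higher, 0.1318), eosinophil markers (3 higher and 5 lower of 12, 0.1855), erythroid markers (5 of 9 lower, 0.2189), metallothioneins (5 of 7 higher, 0.2333) and cytosolic ribosomal proteins (14 of 25 higher, 0.2496) lost theirs too. For 2 lists without a call the signs differed: the monocyte markers (3 higher and 5 lower of 13) had a median of -0.53 and a mean of 9.62e-04, and the Toll-like receptor list (5 higher and 5 lower of 16) had a median of 0.11 but a downward test. The other lists without a call were the T cell, B cell and platelet markers, the NADPH oxidase, the inflammasome and IL-1 family, the apoptosis regulators, the immediate-early genes, and glycolysis with the hypoxia response, with adjusted p values from 0.1535 to 0.8313. The incubation is part of this comparison as well, and the *ACTB* 3 prime minus 5 prime difference moved along (3.43 against 2.67 in unstimulated blood).

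**Figure D1:**
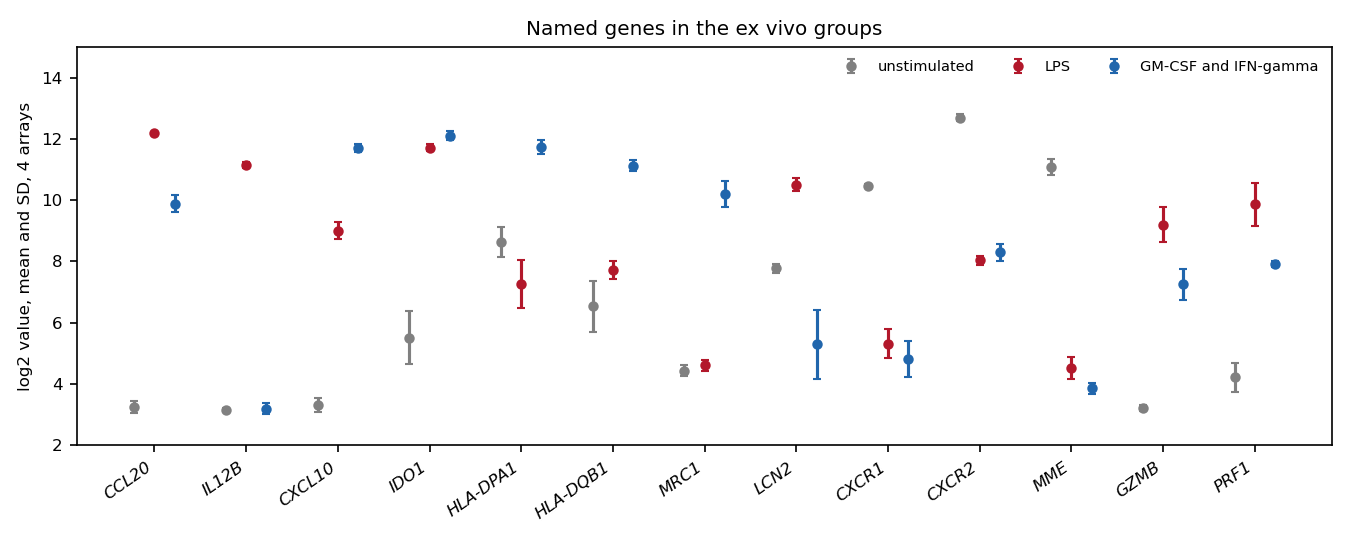
Log2 values (y axis, mean and SD of 4 arrays) of 13 genes in unstimulated, LPS and GM-CSF and IFN-gamma arrays. *HLA-DPA1*, *HLA-DQB1* and *MRC1* were highest after GM-CSF and IFN-gamma, *IL12B* and *LCN2* after LPS, and *CXCR1*, *CXCR2* and *MME* in unstimulated blood.

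How far do both responses overlap, and where do they part? Of the genes called in each, 1744 were higher in both and 1738 lower in both, where independent responses would give 470 and 291, and 67 moved in opposite directions. Both contrasts share the 4 unstimulated arrays, which alone gave a correlation across genes of 0.50 in simulated unchanged groups, against 0.806 observed. The covariance was 1.02 against 0.041 in the simulation. With the unstimulated arrays split 2 and 2, each part serving 1 contrast, the correlation was 0.734 on average and 1267 and 1257 genes were higher or lower in both. Genes are not independent replicates. Both contrasts also share the incubation, which unstimulated blood lacked, and neither the simulation nor the split removes it. The overlap may therefore hold genes that the incubation moved.

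The contrast of the 2 stimuli shares its incubation. *IL12B* was at least 249-fold higher after LPS (11.15 ± 0.09 against 3.19 ± 0.18 log2 units, SD, n = 4 per group), the gap junction gene *GJB2* at least 101-fold and *CSF3*, which encodes G-CSF, 43.6-fold. *LCN2* was 37.3-fold higher after LPS (10.51 ± 0.23 against 5.29 ± 1.13). After GM-CSF and IFN-gamma the genes *MRC1* (48.1-fold), *MSR1*, a scavenger receptor (at least 24.5-fold), and *CD1B*, which presents lipids (at least 23.1-fold), were higher than after LPS, as were the chemokine *CXCL9* (20.8-fold) and the metabolic enzyme gene *FBP1* (at least 44.3-fold). The limma test called 1004 genes higher and 1502 lower after LPS, 514 and 1109 of them by at least 1 log2 unit. The arrays did not overlap for 3855 genes (19.5%), where chance gives 2.86%.

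Of 12 MHC class II genes 10 were lower after LPS than after GM-CSF and IFN-gamma and 0 higher (median -2.79, adjusted p 2.05e-13), with *HLA-DPA1* at -4.47 ± 0.35 (SE) and *HLA-DMA* at -4.07 ± 0.47. Of the interferon-gamma target genes 12 of 21 were lower and 0 higher (17 adjusted over the list alone, median -0.85), such as *CIITA*, the master regulator of class II genes (-3.24 ± 0.48), and *CXCL10* (-2.70 ± 0.20). In the other direction, 13 of 25 type I interferon-stimulated genes were higher after LPS and 0 lower (15 adjusted over the list alone, median 0.65), with *IFIT1* at 3.80 ± 0.17 and *HERC5* at 2.00 ± 0.24. NF-kB targets (10 of 18 higher, 0 lower, median 0.47, *NFKB1* at 1.55 ± 0.25) and cytokines (12 of 23 higher, 3 lower, median 0.69) were also higher after LPS, although the monocyte attractant *CCL7* was lower (-4.33 ± 0.33). All 7 metallothioneins were higher after LPS (median 3.15), *MT1H* by 3.78 ± 0.27.

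Of 26 lists 13 passed in this contrast with the preset correlation and 6 with the estimated one: the MHC class II genes, both interferon lists, the NF-kB targets, the cytokines and the metallothioneins. Cytosolic ribosomal proteins (21 of 25 lower after LPS, median -0.94, with *RPL22* at -1.51 ± 0.26 and *RPL8* at -1.36 ± 0.17) lost their call at an adjusted p of 0.0632, and the secondary and tertiary granule genes (3 higher and 1 lower of 15) at 0.0686. MHC class I genes (5 of 14 lower) and the NADPH oxidase (2 higher and 1 lower of 7, with *NCF4* at 2.15 ± 0.09) lost theirs at 0.1114. Heat shock proteins (5 lower and 1 higher of 10) and monocyte markers (8 lower and 1 higher of 13, median -1.76, with *FCN1* at -3.61 ± 0.26 and *LGALS2* at -3.83 ± 0.59) lost theirs at 0.1178, and NK cell markers (5 of 13 higher, *GZMB* at 1.94 ± 0.32) at 0.1882. No call was made for the Toll-like receptor list, whose median (-0.06) and mean (0.02) differed in sign, for the resting receptors (median -0.02, mean -0.07) or for the JAK-STAT list (median -0.02, mean -0.10), in both of which the test pointed upward. *CISH* (-2.34 ± 0.34) and *PIM2* (1.54 ± 0.16) of the last list moved apart. Primary granule genes, the inflammasome, the apoptosis regulators, the immediate-early genes, glycolysis and the T cell, B cell, eosinophil, platelet and erythroid markers gave adjusted p values from 0.1239 to 0.8509.

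**Figure D2:**
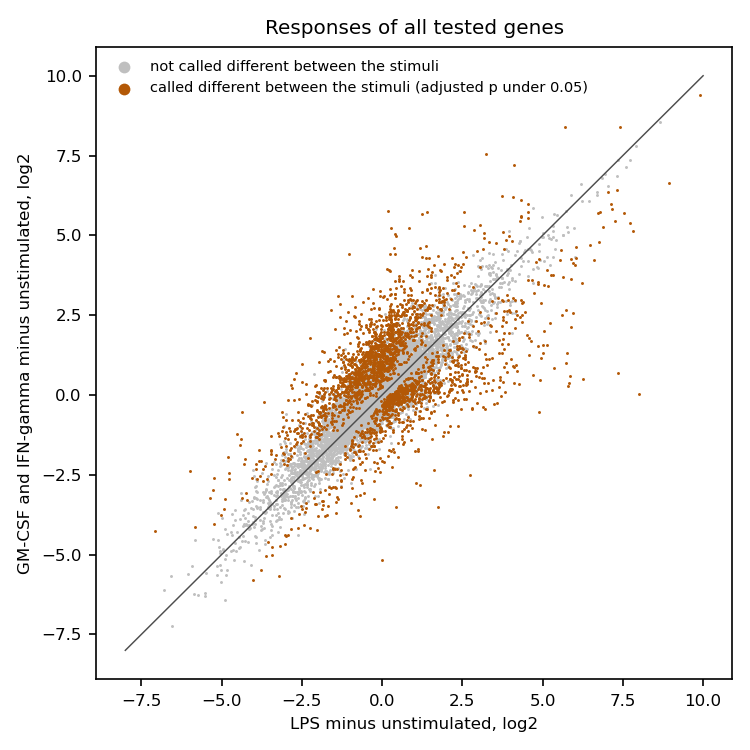
Log2 change of each tested gene after LPS (x axis) and after GM-CSF and IFN-gamma (y axis), both against unstimulated blood, with the line of equal change. Coloured points are the 2506 genes called different between the stimuli.

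Do the isolation methods give different profiles? The limma test with the volunteer as a block called 0 genes, with a smallest adjusted p of 0.295, and 1127 genes had an unadjusted p under 0.05 (660 higher and 467 lower with microfluidics) where chance gives 987. That count was 2336 without 1 of the 5 pairs, 781 to 876 without 1 of the others, and 1766 with array weights. *DUSP1*, a phosphatase induced within minutes by stress, was 1.52-fold lower with microfluidics (12.34 ± 0.27 against 12.94 ± 0.25 log2 units, SD, n = 5 per method, lower in 5 of 5 pairs), and *CXCL8*, a neutrophil chemokine, was 1.75-fold lower in 5 of 5 pairs. *MS4A3*, expressed in granulocyte precursors, was 3.70-fold higher (9.84 ± 1.66 against 7.96 ± 1.32) in 5 of 5 pairs. None of these passed over all genes, with adjusted p values of 0.694, 0.866 and 0.694. In simulated data with the same spread and 50 changed genes per size, the paired test found 36% of genes that differed by 1 log2 unit. It found 100% of those that differed by 2. Changed genes ease the adjusted threshold, so with 0 genes called these shares do not hold for the real data. Some genes named below differed by more than 2 log2 units and were not called. The same sign in all pairs was seen for 1110 genes (5.62%), where chance gives 6.25%.

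Over the immediate-early list alone, 10 of 18 genes were lower with microfluidics (median -0.70) and 0 higher. Examples chosen after their values were seen are the transcription factor genes *FOSB* (-2.87 ± 0.78 SE) and *JUNB* (-0.79 ± 0.13), and *EGR3* (-3.11 ± 0.98). Adjusted over the list alone, 5 of 7 primary granule genes were higher, including *MPO* (2.15 ± 0.44), and so were 3 secondary and tertiary granule genes, *LCN2* (1.88 ± 0.29), *LTF* (1.27 ± 0.31) and *CAMP* (1.25 ± 0.36). Likewise 4 cytokine genes were lower, *CXCL1*, *CXCL2*, *OSM* and *PTGS2*, of which *OSM* differed most (-2.40 ± 0.48). *SOCS3* and *CD69* of the JAK-STAT list were lower, and *HLA-DMB* and *IRAK2* were higher, these genes too being chosen after their values were seen. T cell markers had a median of -1.32 and platelet markers one of 1.00, with 0 genes called in either.

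The list test with the preset correlation passed 15 of 26 lists, but 0 passed with an estimated correlation and 0 with fry. For the immediate-early genes the adjusted p went from 7.20e-16 to 0.2133, for the primary granule genes from 2.85e-08 to 0.3411 and for the T cell markers from 1.84e-08 to 0.3411. The secondary granule genes, the platelet, B cell and NK cell markers, the MHC class II genes, the cytosolic ribosomal proteins and the NADPH oxidase went to 0.3514, the eosinophil markers and the JAK-STAT list to 0.3411, the cytokines and NF-kB targets to 0.2133, and the resting receptors to 0.4634. Without a call were type I interferon-stimulated genes, interferon-gamma target genes, MHC class I genes, the Toll-like receptor list (median -0.06, mean 0.05), the inflammasome, the apoptosis regulators, heat shock proteins, glycolysis (median -0.06, mean 0.01), metallothioneins, and the monocyte and erythroid markers.

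Does microfluidic isolation change the spread between volunteers? The median gene SD over the 5 volunteers was 0.272 log2 units with the density gradient and 0.265 with microfluidics, a difference of -0.0069 (two-sided exact permutation p 0.938). Gene by gene the balance ran the other way, with a higher SD with microfluidics for 10079 genes and a lower one for 9661. The sign of the difference was not stable either: it was 0.0551 with dim genes left out and 0.0438 without 1 of the pairs. The median correlation between arrays of a method was 0.968 and 0.952 (exact permutation p 0.313). With 5 pairs the smallest p possible is 0.0625, so neither could fall below 0.05. Within the ex vivo groups the median gene SD was 0.233 in unstimulated blood, 0.226 after LPS and 0.209 after GM-CSF and IFN-gamma. With dim genes left out it was 0.367, 0.372 and 0.317, so unstimulated blood and LPS changed order.

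**Figure D3:**
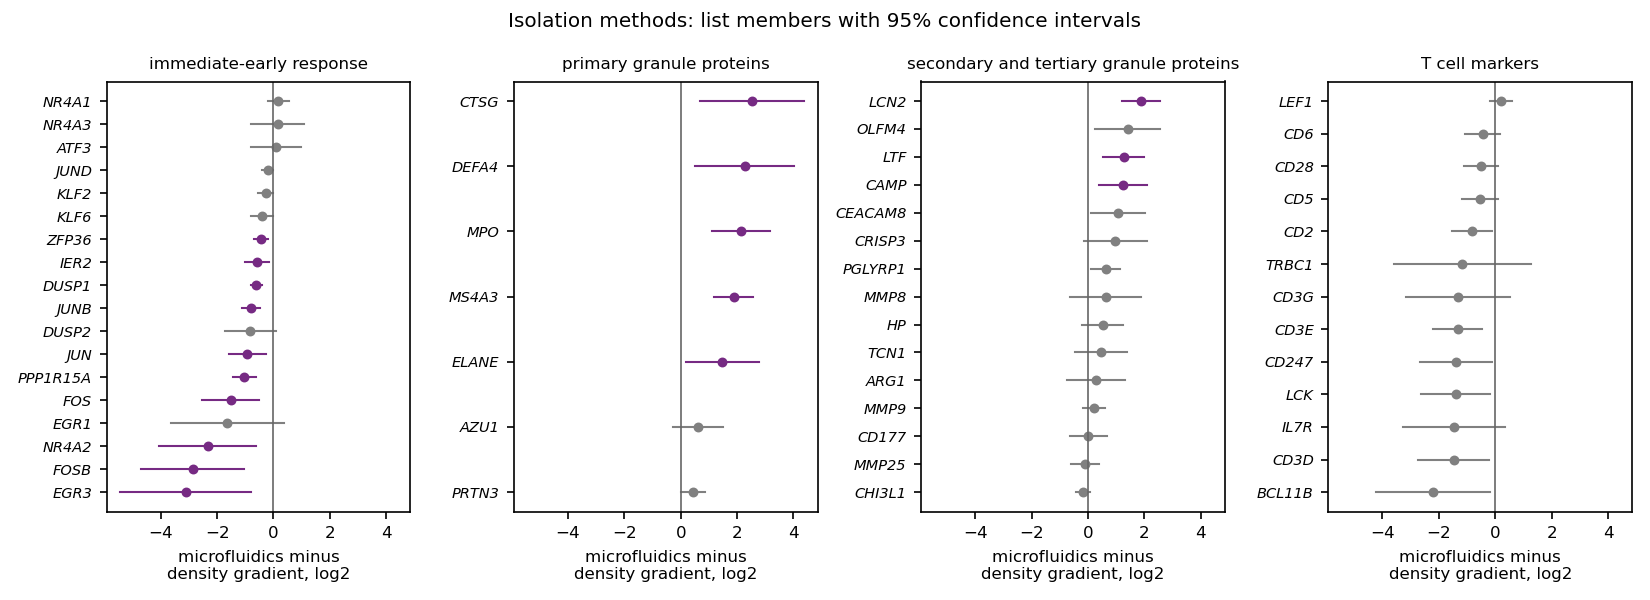
Difference between microfluidics and density gradient (x axis, log2, with 95% confidence intervals, 5 pairs) of the members of 4 lists; darker points passed when adjusted over the list alone. The immediate-early genes lie mostly below 0 and the primary granule genes above 0, and 0 genes passed over all genes.

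**Figure D4:**
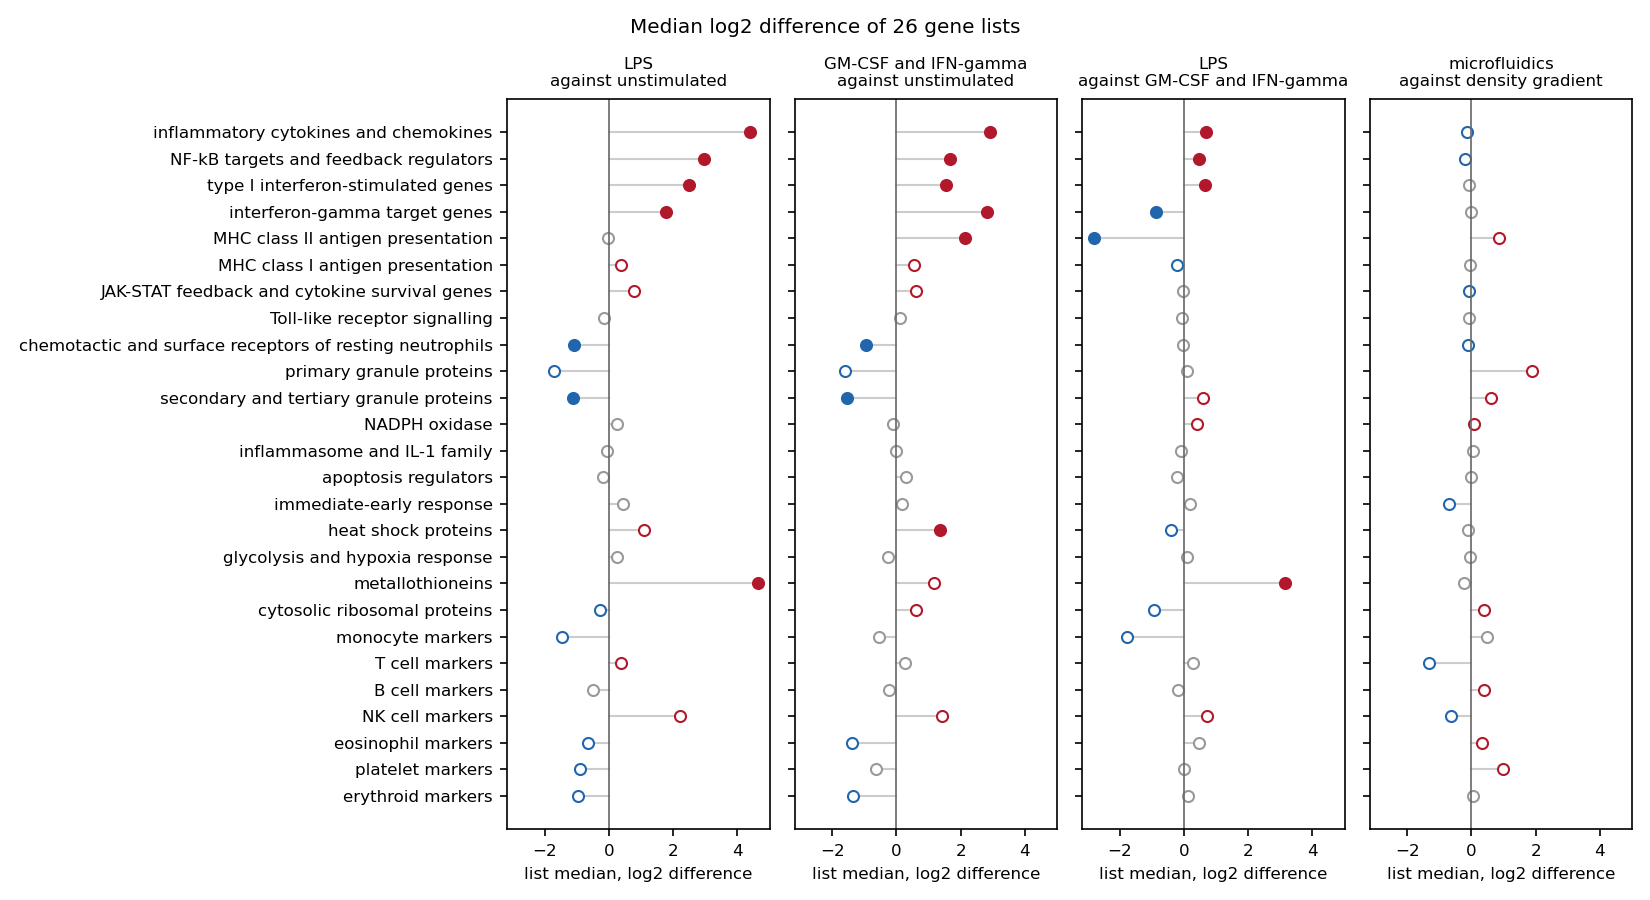
Median log2 difference (x axis) of 26 gene lists in the 4 comparisons. Filled points passed the list test with both correlations, coloured open points with the preset one alone, and grey points with neither: 7, 8, 6 and 0 lists passed with both.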

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

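The tests of explanations given here were all chosen after the results were seen, except that the comparison of the 2 stimuli was planned.

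*LCN2*, which starves bacteria of iron, rose by 2.73 log2 units after LPS and fell by 2.49 after GM-CSF and IFN-gamma, a tested difference of 5.22 between the stimuli. *IFIT1*, an antiviral RNA-binding gene, moved the same way (1.04 and -2.76, difference 3.80), and so did *CHI3L1*, a granule gene (0.74 and -1.01, difference 1.75). *HLA-DPA1* and the gluconeogenesis gene *FBP1* moved the opposite way: -1.37 and 3.10 for the class II gene (difference -4.47), -1.05 and 4.42 for the enzyme (difference -5.47). The enzyme's mean after LPS is taken as near the background, so on that reading its fall and the difference were at least of that size. All 5 genes were called in both contrasts and in the difference between them.

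The MHC class II genes were higher after GM-CSF and IFN-gamma than after LPS, and so were the single genes *MRC1* and *CD1B*. After GM-CSF and IFN-gamma 5 of 13 monocyte markers were lower than in unstimulated blood and 3 higher, with *F13A1* at -2.57 and *FCN1* at -2.37. Unstimulated blood was not incubated, so this cannot decide whether the share of monocytes was higher than after LPS. Between the stimuli 8 of the 13 were lower after LPS and 1 higher (median -1.76), which a higher share after GM-CSF and IFN-gamma would also give. At least 10 class II genes were lower after LPS under quantile normalization and under median centring. The array differences that these remove are therefore not the source. What the unnamed normalization of the deposited values did was not tested. A 3 prime bias of the RNA would follow the *ACTB* difference. This difference was smallest in unstimulated blood, and 9 class II genes were higher after GM-CSF and IFN-gamma than there. That would argue against bias only if bias lowers these probe sets. Its direction for them was not tested, so bias stays open for that rise. Between the stimuli the *ACTB* difference was larger after LPS (4.06 against 3.43), so a part of bias in the lower values after LPS stays open. Also open is whether neutrophils, more monocytes, or monocytes that changed state carry these transcripts: a response to IFN-gamma may be their source, as a hypothesis found and tested on the same data.

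The cytotoxic genes *GZMB*, *PRF1* and *GNLY* rose after LPS by 5.99, 5.65 and 3.78 log2 units in cells captured as neutrophils. A lower share of neutrophils would raise the markers of every other cell type alike. The medians of the monocyte (-1.45), erythroid (-0.95), platelet (-0.89), eosinophil (-0.64) and B cell markers (-0.49) lay below 0. That of the T cell markers lay above 0 (0.37, 3 of 13 higher and 0 lower). The monocyte markers *CD163* (3.85) and *FGL2* (-4.79) moved apart, so such markers do not measure a share of cells alone. A lower share of neutrophils therefore stays open. More unchanged NK cells would raise the other NK cell markers as much as these 3 genes. The median of those other 10 markers was 1.07, with 7 called higher and 0 lower. Their median level in unstimulated blood was 3.62 against 4.11 for all genes, and 4 of the 10 lay above 4.11. The rest are taken as near the background, which would compress their change, and the change of the 4 alone is not given here. More NK cells and NK cells that changed state were therefore not told apart. The capture step itself would remove NK cells, and how many passed it was not measured.

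Immediate-early genes were lower with microfluidics than with the density gradient, with a list median of -0.70, but 0 of 18 members passed over all genes in limma and the list lost its call with an estimated correlation (adjusted p 0.213). Over all genes 1127 had an unadjusted p under 0.05, and 2336 without 1 of the pairs. Under quantile normalization the median was -0.71, but that moved no list median by more than 0.029, so array scaling stays open. Fewer T cells with microfluidics could add to it, since the T cell median was also below 0 in the same 4 of 5 volunteers, and RNA quality stays open, since the *ACTB* difference was lower with microfluidics by -0.16 (exact permutation p 0.125) and that of *GAPDH* higher by 0.14, at the smallest p the design allows (0.0625). Handling time and isolation method go together, so a response of the cells to the density gradient stays open too and untested.

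In 32 of 443 groups of 4 or 5 values, 1 array lay far from the others. Chance flags about 1 in 20 groups, here 22.15. The number is the gap to the nearest array as a share of the whole range. In unstimulated blood these were *GPR84* (0.831), *CAMP* (0.883), *PRG2* (0.938), *IL7R* (0.938), *CCM2L* (0.986), *MSR1* (0.971), *NCF4* (0.900) and the highest value of an array (0.968). After LPS they were *IRAK3* (0.889), *MMP25* (0.912), *CAMP* (0.886), *HBB* (0.912), *F13A1* (0.861), *CCM2L* (0.894), *NFKB2* (0.940) and the *ACTB* difference (0.881). After GM-CSF and IFN-gamma they were *CCL20* (0.852), *CCL2* (0.938), *PLAU* (0.857), *MRC1* (0.856), *F13A1* (0.929), *FBP1* (0.887), *CD1B* (0.907), *RPL22* (0.844) and the lowest value of an array (0.833). With the density gradient they were *FOSB* (0.883), *DEFA4* (0.764), *CD74* (0.769) and the interquartile range (0.833), and with microfluidics *CXCL2* (0.759), *GZMA* (0.774) and the array median (0.75).

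Of the 11721 probe sets that name no gene and entered no comparison, 1518 passed the same test for LPS against unstimulated blood (846 higher and 672 lower), 1395 for GM-CSF and IFN-gamma (492 and 903) and 277 for LPS against GM-CSF and IFN-gamma (176 and 101). The hybridization control probe sets averaged 13.01 log2 units in the volunteer arrays and 3.11 in the ex vivo arrays, a difference of 9.89. No test here uses them, but the background assumed for the ex vivo arrays leans on the lower value.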

How the results depend on the processing

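The list tests that leave out a volunteer pair were chosen after the data were seen; the other alternatives were planned.

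The numbers of genes called in the 3 ex vivo comparisons stayed within 1.5 times their values under quantile normalization, median centring, leaving out dim genes, the median over probe sets, no variance trend, array weights, the replicate number as a block, 8 arrays alone and leaving out each array. Only a minimum of 1 log2 unit moved them further, by its construction: 1634 genes higher after LPS than in unstimulated blood, and 514 higher after LPS than after GM-CSF and IFN-gamma. With the replicate number as a block, 2798 and 2395 genes were higher and lower after LPS, 2938 and 2197 after GM-CSF and IFN-gamma, and 842 and 1335 between the stimuli. Whether the replicate numbers pair the arrays is not known. Deviations of arrays with the same number correlated between -0.075 and 0.050, but the volunteer arrays, which are paired, correlated at only 0.063 within a volunteer. The balance of the LPS response turned over in 3 settings: 2522 genes were higher and 2742 lower with median centring, 2164 and 2346 with dim genes left out, and 1634 and 1867 with a minimum of 1 log2 unit, against 3048 and 2484.

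*NFKB2* lost its call between the stimuli in 7 of 8 fits that leave out an array (adjusted p 0.0512 to 0.0973), which have fewer arrays. With the median over probe sets *IL23A* (0.14, adjusted p 0.184), *CYBB* (-0.53, 0.0532) and *HSPD1* (0.29, 0.678) lost theirs, where other probe sets of the gene differ from the brightest.

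With an estimated correlation the lists called fell to 7 for LPS, 8 for GM-CSF and IFN-gamma, 6 between the stimuli and 0 for the isolation methods, and fry called 0 for the isolation methods. Leaving out a pair gave 13 to 19 lists there with the preset correlation. With fry 20, 20 and 15 lists passed in the ex vivo comparisons, with dim genes left out 14, 13 and 13, and with quantile normalization 15, 16 and 14.

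For the isolation methods each alternative called 0 genes, with or without the volunteer block, except that leaving out a pair gave 0 to 2 lower genes: without 1 of the pairs *CD69* (-3.89) and the zinc finger gene *ZNF836* (-2.82) passed at an adjusted p of 0.0223, and 2336 genes had an unadjusted p under 0.05 against 1127. Both genes were named after their values were seen, and the cause was not tested.

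The difference in spread between the methods was 0.0551 with dim genes left out and ran from -0.0275 to 0.0438 when a pair was left out, so its sign was not stable. The median gene SD in unstimulated blood, after LPS and after GM-CSF and IFN-gamma was 0.367, 0.372 and 0.317 with dim genes left out and 0.214, 0.204 and 0.196 with the median over probe sets. It ran from 0.206 to 0.225, 0.205 to 0.217 and 0.191 to 0.202 when an array was left out. A median SD over fewer arrays runs lower by construction, so these ranges are not comparable with the values from all arrays. The cause of the other shifts was not tested.

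The alternatives on pseudocounts were not run, since the values are on a log scale. Signal near the background limits what dim genes can show.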

Other observations

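Mitochondrial ribosomal proteins, proteasome and chaperonin subunits, and subunits of NADH dehydrogenase and ATP synthase, were higher after GM-CSF and IFN-gamma than after LPS. Of 77 mitochondrial ribosomal protein genes 30 were lower after LPS and 1 higher (median -1.01), *MRPL3* by -3.67 ± 0.38 and *MRPL1* by -3.63 ± 0.42 (SE, n = 4 per group). Also lower after LPS than after GM-CSF and IFN-gamma were 22 of 40 proteasome subunits (1 higher, median -0.67, *PSMB6* at -2.08) and 6 of 9 CCT chaperonin subunits (median -1.31, *CCT4* at -2.80). So were 12 of 19 ATP synthase subunits (median -0.83, *ATP5MC3* at -2.59), 16 of 35 NADH dehydrogenase subunits (1 higher, median -1.19) and 20 of 52 translation initiation factors (1 higher, median -0.69). The *ACTB* 3 prime minus 5 prime difference (4.06 after LPS, 3.43 after GM-CSF and IFN-gamma) and the monocyte markers (8 of 13 lower after LPS, median -1.76) moved along with them, and neither was separated from these families. The CD1 genes, which present lipids to T cells, were lower after LPS in 4 of 5 members, *CD1C* by -4.24 ± 0.50. Against unstimulated blood, 37 mitochondrial ribosomal protein genes were higher after GM-CSF and IFN-gamma and 0 lower (median 1.04). After LPS 13 were higher and 5 lower (median 0.06). Proteasome subunits (17 higher and 6 lower) and initiation factors (21 and 4) were then more often higher. ATP synthase (0 and 6) and NADH dehydrogenase subunits (5 and 10) were more often lower.

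H2A and H2B histone genes were lower after both stimuli than in unstimulated blood, 11 and 14 of 23 (medians -0.69 and -0.81), with *H2AC6* at -3.56 and -3.51. Here too the *ACTB* difference moved along (2.67 in unstimulated blood), as did the monocyte markers after LPS (median -1.45). Neither these nor the incubation that both groups share was separated from the stimuli. Vacuolar ATPase subunits, which acidify lysosomes, were higher in 11 of 25 genes after LPS and in 11 after GM-CSF and IFN-gamma, with 0 lower in either. *ATP6V1C1* rose after both (2.57 and 2.16). The vacuolar ATPase calls were lost with an estimated correlation (adjusted p 0.0686 and 0.0685).

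These families and the tests of them were chosen after the data were seen. First 27 symbol patterns were scanned, and then 1 histone pattern was redrawn. All 28 were tested in the 4 comparisons and adjusted together over 112 tests. With an estimated correlation the adjusted p between the stimuli was 0.0069 for the mitochondrial ribosomal proteins and the proteasome, 0.0084 for the chaperonin, the NADH dehydrogenase and the initiation factors, 0.01 for the ATP synthase and 0.0146 for the CD1 genes. For H2A and H2B histones it was 0.0231 after LPS and 0.0146 after GM-CSF and IFN-gamma. The directions given here were the same under quantile normalization and median centring, with 1 exception. The median of the mitochondrial ribosomal proteins after LPS against unstimulated blood (0.06) was -0.0025 with median centring. Histone genes resemble one another, and whether their probe sets match several of them was not tested.

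Other splits of the same arrays were tested for each comparison, also after the results were seen. For LPS against unstimulated blood, GM-CSF and IFN-gamma against unstimulated blood, and LPS against GM-CSF and IFN-gamma, 1 of 35 splits, the real one, gave as many genes: 5532, 5361 and 2506 genes, where the highest other split gave 1, 1 and 2. For lists with the preset correlation 1 of 35 splits again gave as many, but by a narrow margin: 18, 16 and 13 lists against 16, 15 and 12 in the highest other split. With the estimated correlation, the real splits gave 7, 8 and 6 lists and the other splits 0. Of the 34 other splits 16 exchange 1 array per group and keep part of the real difference. The 18 that exchange 2 keep none of it, and called at most 3 lists with the preset correlation in each of these comparisons. They gave medians of 550.5, 460.5 and 588.5 genes at an unadjusted p under 0.05 in limma, where chance gives 987. In such splits the real difference adds to the spread within the groups, which keeps calls low. The splits therefore cannot exclude chance.

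For the isolation methods 16 splits part every pair, too few for a share under 0.05. The real split gave 0 genes, as did all 16, and 15 lists, where 2 of 16 gave as many and the highest other gave 16. Among 84 other splits drawn, up to 21 genes and 17 lists passed. List medians were also set against the 16 splits. The real split gave the median furthest from 0 for 5 of 26 lists: the immediate-early genes (-0.70, highest other 0.58), the primary granule genes (1.89, 1.58), the MHC class II genes (0.85, 0.84), the NF-kB targets (-0.19, 0.15) and the monocyte markers (0.48, 0.32). For the T cell markers 1 other split gave as large a median (-1.32).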
